A study of Homo sapiens with 48 samples.

How the data were processed

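MicroRNAs were measured in 48 human tissue samples of a study of cutaneous squamous cell carcinoma, a skin cancer of keratinocytes. Per the labels, RNA was extracted with a commercial kit, and small RNAs were prepared for the NanoString nCounter, which ligates a sequence tag to each mature miRNA and counts fluorescent barcodes of hybridised probes without amplification. The deposited values are whole-number counts per miRNA probe, with 800 probes in each of the 48 samples. The counting software, and any background, lane or ligation correction before deposit, were not given in the sources used here. Control probes were not used here, so the background of a library was taken as the median of all its probes.

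Each sample was grouped by 2 labels, the class in its title (metastatic or non-metastatic) and its tissue (normal skin, primary tumour or metastasis). This gave 5 groups with 47 samples: 8 metastases, 11 primary tumours and 11 normal skin samples of the metastatic class, and 9 primary tumours and 8 normal skin samples of the non-metastatic class. The title and tissue of 1 further sample contradicted each other, and it entered no comparison. The labels do not tie samples to patients, so samples were treated as unpaired, and p-values measure the spread between these samples, some of which may come from 1 patient. No 2 of the 202 pairs of libraries within a group held identical values, and the smallest chi-square per degree of freedom between such a pair was 6.14, so no library was treated as a repeat.

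Total counts per library ranged from 69455 to 803634, and the median probe had 8 to 25 counts. The probe for miR-4454 took a mean of 60.8% of the counts of a library (range 40.3% to 75.1%). Probes with at least 20 counts in at least 8 samples were kept, which left 387 of 800; 124 probes were below 20 in every library. Of the probes on the panel, 10 name several miRNAs with near-identical sequences and cannot tell them apart, and members of 1 family that differ by few bases can share signal.

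Counts were analysed with edgeR 4.0.16 in R 4.3.3: TMM scaling, 1 fit with 5 group means, the quasi-likelihood F test, a prior count of 0.125, and Benjamini-Hochberg adjustment at 0.05 over the kept probes of each comparison. A miRNA called higher or lower below had an adjusted p under that level. Tests were two-sided. Fold changes are on the log2 scale, and their standard errors (SE) were approximated as the log2 fold change divided by the square root of F. Levels are TMM-scaled CPM (counts scaled to a common library total), given as mean ± SD. The 6 comparisons were primary tumour against normal skin with both classes weighted equally, the primary tumours of the classes, metastasis against metastatic-class primary tumour, metastasis against metastatic-class normal skin, normal skin of the classes, and the difference between the classes in the tumour-minus-normal change. The fit was tested on simulated counts of the 387 probes with 100 probes changed at each size and 187 left unchanged. No batch, class difference in signal over background or outlying library was simulated, so recovery in the real data may be lower. A 2-fold change was recovered in 95%, 79%, 78%, 80%, 82% and 47% of changed probes in these 6 comparisons in that order, and a 4-fold change in 100%, 100%, 99%, 99%, 99% and 87%.

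Lists of miRNAs were tested with camera (limma 3.58.1) at a preset correlation of 0.01 between miRNAs, adjusted over the lists with at least 3 kept members, and again with an estimated correlation and with fry. The 19 lists were keratinocyte-enriched, leukocyte-enriched, red-cell-enriched, skeletal-muscle-enriched, fibroblast- and smooth-muscle-enriched, endothelial-enriched, neural-enriched and melanocyte-enriched miRNAs, the let-7, miR-17-92 and miR-34 families, the miR-183 cluster, the miR-99a/let-7c/125b-type clusters, miRNAs reported higher and lower in squamous carcinoma in earlier literature, the DLK1-DIO3 imprinted cluster, the chromosome 19 placental cluster, entries that resemble tRNA or rRNA fragments, and candidates recalled from the published study of these samples. The last list was chosen on these samples and is not independent evidence. Of the lists, 15 had enough kept members. The groups, tests, lists and the rule for named miRNAs were fixed before the data were examined. That rule took the 8 highest and 8 lowest fold changes among called miRNAs of a comparison, up to 4 members of each list with the smallest p, the kept candidates, and, where fewer than 5 miRNAs were called, the 5 with the smallest p. Of the named miRNAs the text gives those that carry a group's result.

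A technical split of the libraries was found in the values. The probe for miR-302d-3p had 111 to 192 counts in 12 libraries and 53 to 98 in 36, and the median background was 18.5 counts in the former and 11 in the latter. These are called the higher-background and lower-background batch. The threshold between them was set at 100 counts after the data were examined. The batches were spread unevenly: of the higher-background libraries, 7 were metastatic-class normal skin, 2 were metastatic-class primary tumours, 2 were metastases, 1 was non-metastatic-class normal skin and 0 were non-metastatic-class primary tumours.

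Alternatives planned at the start were no scaling, scaling to the geometric mean of the 100 most abundant probes, quantile normalization, median-ratio size factors, no filter, a minimum of 50 counts in at least 8 samples (153 probes), a prior count of 5, DESeq2 1.42.0, limma on log2 counts scaled by TMM to the mean library with pseudocounts of 1, 0.5 and 16, array weights, only the groups compared, log2 total as a covariate, no class term, and the title number as a block. Alternatives added after the data were examined were the batch as a block, each batch alone, subtraction of each library's median count, the abundant-probe scaling with the batch block or the stricter filter, and each library left out in turn. Signal over background is the geometric mean of the 100 most abundant probes of a library divided by its TMM-scaled total, relative to the mean library; TMM follows the many probes near background, so this ratio says how far abundant miRNAs stand above them. Single measures per library were compared with exact permutation tests. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.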

Results

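MicroRNA counts of 47 skin and tumour samples were compared between metastases, primary tumours and normal skin in cutaneous squamous cell carcinoma, in a metastatic and a non-metastatic class. Of the 800 probes, 387 were kept. miR-205-5p, which is abundant in keratinocytes, averaged 28304 ± 15775 CPM in the 20 primary tumours and 25985 ± 18230 CPM in the 19 normal skin samples.

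The libraries of the classes differed in how much miRNA signal they held. Total counts had a median of 214427 (138170 to 332312) in the 11 metastatic-class primary tumours and 115953 (69455 to 163045) in the 9 non-metastatic-class primary tumours. This was a 1.92-fold difference of geometric means (exact permutation p = 0.000149, adjusted p = 0.00267 over 32 such tests). Within the lower-background batch, which held 9 libraries of each, it was 1.80-fold (exact permutation p = 0.000535, adjusted p = 0.00428). The abundant miRNAs also stood 1.63-fold further above the background in the metastatic class (exact permutation p = 0.000167, adjusted p = 0.00267). Within the lower-background batch this was 1.62-fold (exact permutation p = 0.00074, adjusted p = 0.00461). Normal skin of the metastatic class had 1.66-fold higher totals than that of the other class (exact permutation p = 0.0248, adjusted p = 0.113). Within the lower-background batch that ratio was 1.31 (4 against 7 libraries, exact permutation p = 0.236). Metastases and metastatic-class primary tumours differed by 1.14-fold in totals (exact permutation p = 0.383).

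**Figure D1:**
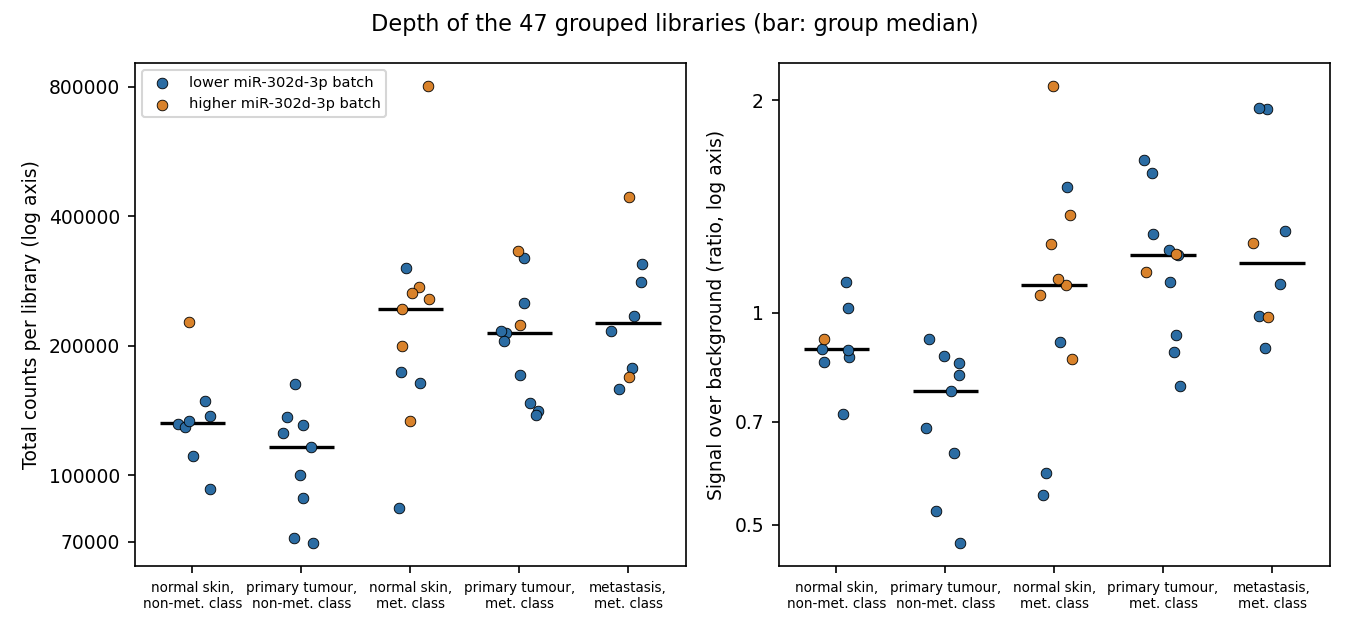
Total counts per library (left) and signal over background as a ratio to the mean library (right), both on log axes, in the 5 groups, with 1 point per library coloured by batch and a bar at the group median. The median total was 214427 counts in metastatic-class and 115953 in non-metastatic-class primary tumours, and the median signal over background was 1.21 and 0.774.

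Primary tumours had lower levels than normal skin of 8 miRNAs, with both classes weighted equally (20 tumours, 19 normal skin samples). miR-145-5p, which is abundant in smooth muscle cells and fibroblasts, fell by 1.68 on the log2 scale (SE 0.35), from 5258 ± 4699.7 to 1759 ± 979 CPM. It lay below the normal median in 19 of 20 tumours (adjusted p = 0.00504, edgeR). miR-195-5p fell by 1.25 (SE 0.28, 20 of 20 tumours, adjusted p = 0.00853). miR-497-5p, which comes from the same gene cluster, fell by 0.96 (SE 0.26, 18 of 20, adjusted p = 0.0326). miR-26a-5p fell by 1.22 (SE 0.30, 16 of 20), miR-100-5p fell by 1.15 (SE 0.28, 19 of 20) and miR-214-3p fell by 0.97 (SE 0.24, 16 of 20), each with an adjusted p = 0.0125. miR-518b, a member of the chromosome 19 placental cluster, fell by 0.89 (SE 0.23, 19 of 20, adjusted p = 0.0238). miR-877-5p fell by 0.69 (SE 0.19, 19 of 20, adjusted p = 0.0326). It entered 17 of the 20 alternatives, as it had too few counts for the stricter filter and the background subtraction. No miRNA was called higher by edgeR (0, against 3 by DESeq2, 0 by limma and 22 by limma with array weights), but edgeR called 9 higher without a class term and 4 without metastatic-class normal skin replicate 1. In either direction, 62 had an unadjusted p under 0.05.

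Single libraries carried some of these calls. miR-518b stood at -0.75 without metastatic-class normal skin replicate 27 (adjusted p = 0.0638). The call of miR-497-5p ended without any of 6 libraries, furthest without non-metastatic-class normal skin replicate 1 (-0.74, adjusted p = 0.118). That of miR-877-5p ended without any of 10, furthest without non-metastatic-class normal skin replicate 14 (-0.52, adjusted p = 0.153). The number of called miRNAs was 5 without metastatic-class normal skin replicate 27 and 15 (4 higher, 11 lower) without replicate 1 of that group.

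The 8 kept miRNAs enriched in fibroblasts and smooth muscle all had negative log2 fold changes (median -0.92, -0.81 with the batch as a block). Over all libraries the list fell in tumours (camera adjusted p = 8.92e-10, and 0.0476 with an estimated correlation). Within the lower-background batch the median was -0.38, and the list passed at the preset correlation (camera adjusted p = 0.00149). A permutation of the libraries of that batch did not pass (difference of the mean log2 level of the 8 miRNAs -0.435, 18 against 11 libraries, exact permutation p = 0.139). Of them, 4 were called, miR-145-5p, miR-195-5p, miR-214-3p and miR-497-5p, and 6 passed when adjusted over the list alone. The miR-99a, let-7c and miR-125b clusters fell as a list (median -0.82, -0.92 with the batch as a block, -0.47 within the lower-background batch, where it did not pass, camera adjusted p = 0.117; over all libraries camera adjusted p = 0.00316; adjusted p = 0.198 with an estimated correlation). Of 6 kept members, 1 was called, miR-100-5p, and 4 passed over the list alone. miR-125b-5p stood at -1.02 (SE 0.32, 19 of 20 below the normal median, adjusted p = 0.0948) and miR-99a-5p at -1.10 (SE 0.40, 18 of 20, adjusted p = 0.150). miRNAs reported lower in squamous carcinoma in earlier literature fell as a list too (13 of 14 negative, median -0.44, camera adjusted p = 2.49e-07; adjusted p = 0.0702 with an estimated correlation). With the batch as a block its median was -0.61 (camera adjusted p = 5.13e-05) and within the lower-background batch -0.13 (camera adjusted p = 0.0654). Of these, 4 were called and 6 passed over the list alone. The called were miR-26a-5p, miR-100-5p, miR-145-5p and miR-214-3p, of which the last 3 are also in the lists above.

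Those reported higher in squamous carcinoma rose as a list (13 of 13 positive, median 0.48, 0.39 with the batch as a block, 0.25 within the lower-background batch; camera adjusted p = 2.31e-05; adjusted p = 0.0637 with an estimated correlation). edgeR called 0 of them, and 2 passed over the list alone. miR-135b-5p was above the normal median in 20 of 20 tumours (log2 fold change 1.06, SE 0.42, adjusted p = 0.196; 1.52 without metastatic-class normal skin replicate 1, adjusted p = 0.00775) and miR-130b-3p in 18 of 20 (0.53, SE 0.18, adjusted p = 0.118). The miR-17-92 family, a set of proliferation-associated miRNAs, rose as a list (9 of 11 positive, median 0.48, but 0.09 without scaling; camera adjusted p = 0.0134; adjusted p = 0.438 with an estimated correlation). Of its members 0 were called and 3 passed over the list alone. miR-19a-3p stood at 0.60 (SE 0.20, 17 of 20 above, adjusted p = 0.107; 0.71 without that replicate 1, adjusted p = 0.00775). miR-18a-5p stood at 0.48 (SE 0.17, 17 of 20, adjusted p = 0.118; 0.59 without non-metastatic-class normal skin replicate 13, adjusted p = 0.0310). Keratinocyte-enriched miRNAs (7 kept, median 0.48, but 0.19 with the batch as a block and 0.03 without scaling; camera adjusted p = 0.299) and the miR-183 cluster (3 kept, median 0.48, but 0.18 without scaling; camera adjusted p = 0.299) did not pass. Nor did melanocyte-enriched miRNAs (4 kept, median -0.39, but -0.15 within the lower-background batch; camera adjusted p = 0.101) and the let-7 family (9 kept, median -0.23, but 0.06 within the lower-background batch; camera adjusted p = 0.0703). Lists too small to test were endothelial-enriched (2 of 2 negative, 0 called, 1 over the list alone, median -0.54) and red-cell-enriched (2 of 2 negative, 0 called, median -0.45).

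With the batch as a block edgeR called 0 miRNAs (42 with an unadjusted p under 0.05; other tools were not run with it), and the median log2 fold change of the 8 went from -1.06 (SE 0.27) to -0.85 (SE 0.28). Within the lower-background batch none was called (0 of 8, median -0.51): miR-145-5p stood at -0.74, miR-195-5p at -0.56, miR-26a-5p at -0.19, miR-100-5p at -0.84, miR-214-3p at -0.40, miR-497-5p at -0.61, miR-518b at -0.39 and miR-877-5p at -0.46, and over all libraries scaling to the most abundant probes gave 4 higher and 7 lower.

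Between the primary tumours of the classes, 51 miRNAs were higher and 11 lower in the metastatic class (11 against 9 tumours). miR-4286 rose 13.5-fold, from 2285 ± 1845 to 30811 ± 25343 CPM (log2 fold change 3.75, SE 0.77). It was above the median of the other class in 9 of 11 tumours (adjusted p = 0.00105, edgeR). miR-21-5p, a miRNA raised in many carcinomas, rose 4.94-fold, from 4309 ± 3394 to 21298 ± 14576 CPM (2.30, SE 0.56, 10 of 11, adjusted p = 0.0049). miR-223-3p, which is abundant in myeloid cells, rose by 2.10 (SE 0.53, 10 of 11, adjusted p = 0.00537), and miR-421 by 1.84 (SE 0.36, 10 of 11, adjusted p = 0.00103). In 11 of 11 metastatic-class tumours miR-29b-3p (1.71, SE 0.45, adjusted p = 0.00795), miR-26a-5p (2.83-fold, SE 0.43 on the log2 scale, adjusted p = 0.0131) and miR-361-5p (1.33, SE 0.31, adjusted p = 0.00363) were above the median of the other class.

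The let-7 family, which is linked to differentiation, rose as a list (9 of 9 positive, median 1.24, but 0.52 under scaling to the most abundant probes; camera adjusted p = 9.57e-05; adjusted p = 0.349 with an estimated correlation). Of its members 5 were called and 7 passed over the list alone. They were let-7f-5p (1.67, SE 0.41, 10 of 11 tumours, adjusted p = 0.00506), let-7i-5p (1.39, SE 0.41, 10 of 11, adjusted p = 0.0157) and let-7g-5p (1.36, SE 0.39, 10 of 11, adjusted p = 0.0131). Also called were let-7d-5p (1.26, SE 0.33) and miR-98 (1.24, SE 0.33), each in 11 of 11 with an adjusted p = 0.00795. The miR-17-92 family rose too (8 of 11 positive, median 0.81, but 0.08 under scaling to the most abundant probes; camera adjusted p = 0.00498; adjusted p = 0.349 with an estimated correlation), with 6 called and 6 over the list alone. Among these were miR-106b-5p (1.79, SE 0.35, 9 of 11, adjusted p = 0.00103) and miR-19b-3p (1.72, SE 0.37, 10 of 11, adjusted p = 0.00124). The shared probe of miR-20a-5p and miR-20b-5p stood at 1.57 (SE 0.42, 9 of 11, adjusted p = 0.00811).

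Both lists from the squamous carcinoma literature rose (each adjusted p = 0.349 with an estimated correlation). miRNAs reported higher had a median of 0.55 (13 of 13 positive, camera adjusted p = 0.0172), but of -0.17 under scaling to the most abundant probes. Of these, 3 were called and 3 passed over the list alone: miR-21-5p, miR-223-3p and miR-424-5p (1.11, SE 0.38, 9 of 11, adjusted p = 0.0391). miRNAs reported lower had a median of 0.75 (0.07 under that scaling, 13 of 14 positive, camera adjusted p = 0.00628). Of these, 5 were called and 5 passed over the list alone, including miR-29a-3p (1.58, SE 0.39, 10 of 11, adjusted p = 0.00506). The fibroblast and smooth muscle list rose (7 of 8 positive, median 0.76, but 0.10 under that scaling; camera adjusted p = 0.0349; adjusted p = 0.397 with an estimated correlation). It had 1 called and 1 over the list alone, the shared probe of miR-199a-3p and miR-199b-3p (1.86, SE 0.54, 10 of 11, adjusted p = 0.0145), which stood at 1.38 without metastatic-class primary tumour replicate 2 (adjusted p = 0.0603). Under quantile normalization 0 lists passed with camera, against 5 under TMM (8 with fry). camera sets a list against all other kept probes, many of them near background. Abundant miRNAs stood 1.63-fold further above background in this class, so a list of abundant miRNAs could rise for that reason alone. This was not tested for the 5 lists, and 2 lists with opposite directions in the literature both rose.

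The keratinocyte-enriched miRNAs did not pass as a list (median 1.23, but 0.50 under scaling to the most abundant probes and 0.42 under quantile normalization; camera adjusted p = 0.140), but 3 of 7 were called and 4 passed over the list alone. These belong to the miR-200 family, which restrains ZEB1 and ZEB2: miR-200a-3p (1.68, SE 0.43, 8 of 11, adjusted p = 0.00574), miR-141-3p (1.40, SE 0.42, 7 of 11, adjusted p = 0.0167) and miR-429 (1.34, SE 0.40, 10 of 11, adjusted p = 0.0167). Without metastatic-class primary tumour replicate 17 miR-141-3p stood at 0.99 (adjusted p = 0.0785), and without replicate 15 miR-429 stood at 0.61 (adjusted p = 0.176). Of the miR-183 cluster 2 of 3 were called and 3 passed over the list alone (median 1.16, but 0.45 under scaling to the most abundant probes; camera adjusted p = 0.0630). miR-182-5p rose by 1.28 (SE 0.42, 10 of 11, adjusted p = 0.0300), and its call ended without any of 6 libraries, furthest without replicate 15 (1.03, adjusted p = 0.0830). miR-96-5p rose by 1.12 (SE 0.36, 8 of 11, adjusted p = 0.0229), and its call ended without either of 2 libraries, furthest without replicate 17 (0.72, adjusted p = 0.111). Leukocyte-enriched miRNAs had a median of 0.68, but of -0.06 under scaling to the most abundant probes and -0.19 under quantile normalization (camera adjusted p = 0.0630). Of these, 2 of 6 were called and 2 passed over the list alone, miR-223-3p and miR-342-3p (0.92, SE 0.28, 10 of 11, adjusted p = 0.0183; -0.01 under quantile normalization).

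miR-451a, a red-cell miRNA and 1 of 2 kept from its list, rose by 2.97 (SE 0.92, 6 of 11, adjusted p = 0.0208). Without metastatic-class primary tumour replicate 2 it stood at 2.35 (adjusted p = 0.0683). miR-204-5p, which is abundant in melanocytes, rose by 2.73 (SE 0.81, 5 of 11, adjusted p = 0.0167) and stood at 0.37 without replicate 15 (adjusted p = 0.737). Its list had 1 of 4 called (median -0.13, 0.33 without scaling, mean 0.44; camera adjusted p = 0.676). miR-630 rose by 2.37 (SE 0.67, 10 of 11, adjusted p = 0.0131) and stood at 1.14 without replicate 19 (adjusted p = 0.171). miR-9-5p, a neural miRNA, rose by 1.28 (SE 0.43, 5 of 11, adjusted p = 0.0325), and its call ended without any of 6 libraries, furthest without replicate 2 (0.91, adjusted p = 0.137). Its list had 1 of 4 called (median -0.04, 0.51 without scaling, mean 0.24; camera adjusted p = 0.971).

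Of the 8 candidates recalled from the published study of these samples, which are not independent evidence, 3 were called and 3 passed over the list alone (median 0.71, but 0.0038 under scaling to the most abundant probes and 0.13 under quantile normalization; camera adjusted p = 0.0630). These were miR-4286, miR-200a-3p and miR-148b-3p (0.92, SE 0.28, 9 of 11, adjusted p = 0.0208). The call of miR-148b-3p ended without either of 2 libraries, furthest without non-metastatic-class primary tumour replicate 6 (0.81, adjusted p = 0.0514). miR-148a-3p stood at 1.36 (11 of 11, adjusted p = 0.104). miR-150-5p stood at 0.50, miR-205-5p at 0.32 and miR-4516 at -0.28 (each adjusted p = 0.644), and miR-1915-3p at -0.18 (adjusted p = 0.776). Single libraries moved these: miR-4516 stood at 0.35 without non-metastatic-class primary tumour replicate 8 and miR-205-5p at 0.56 without replicate 2 of that group. Without metastatic-class primary tumour replicate 19 miR-150-5p stood at 0.06 and miR-1915-3p at -0.60. The DLK1-DIO3 imprinted cluster had 0 of 26 called (median 0.04, -0.66 under scaling to the most abundant probes, camera adjusted p = 0.875). The chromosome 19 placental cluster had 0 of 11 (median -0.18, 0.28 without scaling, camera adjusted p = 0.0855). The miR-99a, let-7c and miR-125b clusters had 0 of 6 (median 0.14, -0.52 under scaling to the most abundant probes, camera adjusted p = 0.717). Entries that resemble tRNA or rRNA fragments had 1 of 6, miR-4286 (median 0.03, -0.59 under scaling to the most abundant probes, camera adjusted p = 0.676). Lists too small to test were endothelial-enriched (2 kept, 0 called, median 0.37), skeletal-muscle-enriched (1 kept, 0 called, -0.33), red-cell-enriched (2 kept, median 1.37) and the miR-34 family (1 kept, 0 called, miR-34a-5p at 0.71, adjusted p = 0.243).

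The 11 lower miRNAs were near background, with median counts of 8 to 24 over these 20 tumours and 9 of the 11 below 20, as were 10 of the 51 higher. miR-627 fell by 0.80 (SE 0.23, adjusted p = 0.0132) and miR-891b fell by 0.78 (SE 0.23, adjusted p = 0.0167), each below the other median in 11 of 11 tumours. miR-187-3p fell by 0.89 (SE 0.30, 10 of 11, adjusted p = 0.0325), and its call ended without any of 6 libraries, furthest without non-metastatic-class primary tumour replicate 8 (-0.51, adjusted p = 0.197). miR-3195 fell by 1.42 (SE 0.48, 5 of 11, adjusted p = 0.0325), and its call ended without any of 3 libraries, furthest without the same replicate 8 (0.26, adjusted p = 0.635).

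The split into higher and lower moved with the scaling: 26 higher and 190 lower under scaling to the most abundant probes, 84 and 0 without scaling, 25 and 21 under quantile normalization, 31 and 16 with the stricter filter and 4 and 1 with log2 total as a covariate. With the stricter filter all 31 higher but 0 of the lower were shared with the TMM result over all kept probes. With the batch as a block there were 52 higher and 12 lower, 50 of the higher shared with the unblocked result, and within the lower-background batch 46 and 20.

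**Figure D2:**
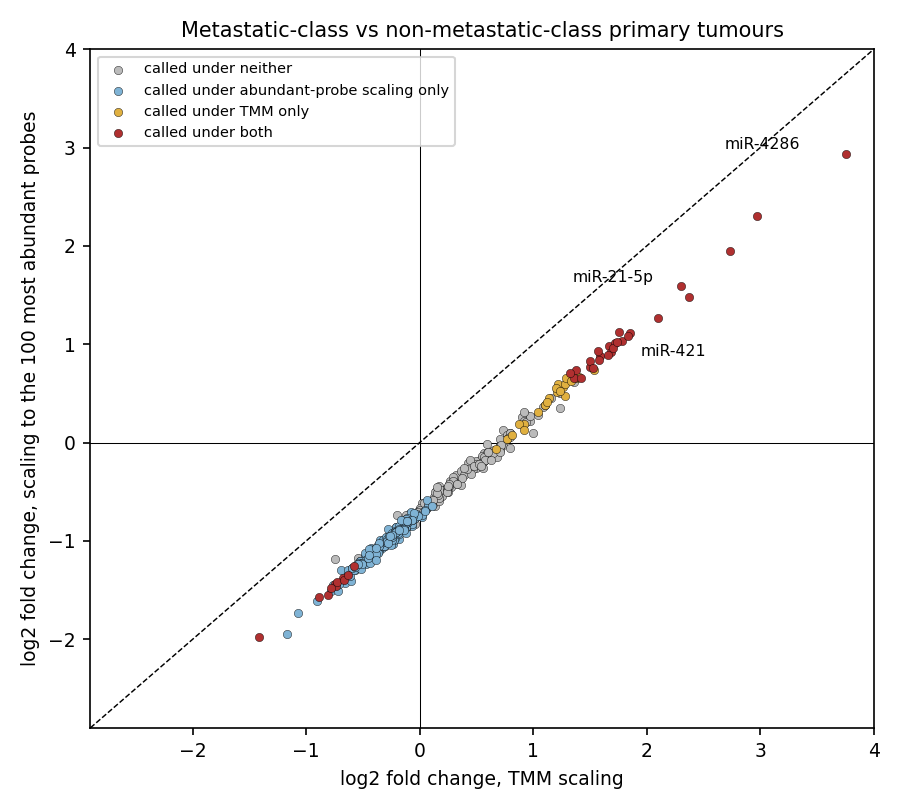
Log2 fold change between metastatic-class (n = 11) and non-metastatic-class (n = 9) primary tumours of the 387 kept probes under TMM scaling (horizontal) and under scaling to the 100 most abundant probes (vertical), coloured by the scalings under which a probe was called, with a dashed line where both are equal. TMM gave 51 higher and 11 lower, the abundant-probe scaling 26 higher and 190 lower, and 26 miRNAs were higher under both.

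Metastases differed from metastatic-class primary tumours in 2 called miRNAs (8 against 11 samples). miR-375, known from neuroendocrine cells, had a log2 fold change of 2.55 (SE 0.51, 406 ± 945 against 68.2 ± 22.1 CPM). It was above the primary median in 3 of 8 metastases (adjusted p = 0.00255, edgeR), and its median counts were 15 and 11, near background. miR-148a-3p had one of 2.79 (SE 0.60, 9044 ± 22002 against 1303 ± 883 CPM, 5 of 8, adjusted p = 0.00433). Without metastasis replicate 16 they stood at 0.08 and -0.04 (adjusted p = 0.999 for each). edgeR then called 0 miRNAs; with it 20 had an unadjusted p under 0.05, and DESeq2 and limma called 0. miR-29c-3p (1.62, SE 0.43, 3 of 8, adjusted p = 0.0614) and miR-30a-5p (1.47, SE 0.41, 4 of 8, adjusted p = 0.0647) did not pass, and without replicate 16 they stood at 0.34 and 0.35 (adjusted p = 0.999 for each).

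Fibroblast- and smooth-muscle-enriched miRNAs rose as a list in metastases (8 of 8 positive, median 0.63, camera adjusted p = 0.00879). The adjusted p was 0.468 with an estimated correlation and 0.0743 without metastasis replicate 16. Of them 0 were called and 0 passed over the list alone; miR-195-5p stood at 0.95 (adjusted p = 0.694; 0.46 without replicate 7) and miR-145-5p at 0.88 (adjusted p = 0.995; 0.20 without replicate 16). The miR-99a, let-7c and miR-125b clusters rose as a list (5 of 6 positive, median 0.78, but 0.48 under quantile normalization; camera adjusted p = 0.0217). The adjusted p was 0.434 with an estimated correlation and 0.293 without replicate 16. Here 0 were called and 2 passed over the list alone, and miR-99a-5p stood at 1.61 (adjusted p = 0.463), but at 0.92 without replicate 16. Leukocyte-enriched miRNAs fell as a list (4 of 6 negative, median -0.06, but 0.12 without scaling; camera adjusted p = 0.00773; adjusted p = 0.387 with an estimated correlation). Of these 0 were called and 0 passed over the list alone; miR-223-3p stood at -1.21 (adjusted p = 0.773) and miR-155-5p at -0.13 (adjusted p = 0.995; -0.33 without replicate 22).

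miRNAs reported higher in squamous carcinoma fell as a list in metastases (9 of 13 negative, median -0.14, camera adjusted p = 0.000601; adjusted p = 0.326 with an estimated correlation), with 0 called and 0 over the list alone. Those reported lower rose (12 of 14 positive, median 0.79, but 0.42 under quantile normalization; camera adjusted p = 0.000601). The adjusted p was 0.387 with an estimated correlation and 0.110 without metastasis replicate 16. Among them 1 was called, miR-375, and 4 passed over the list alone. Of the 8 candidates, which are not independent evidence, 1 was called and 1 passed over the list alone, miR-148a-3p. Their median was 0.05 (-0.34 under quantile normalization), while the test pointed down (camera adjusted p = 0.900). The count of calls was 2 with the batch as a block, 3 within the lower-background batch, 0 within the higher-background batch, and 4 without any of metastasis replicates 6, 13, 14, 22 and 25 or metastatic-class normal skin replicate 27.

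Against metastatic-class normal skin, metastases had 7 higher miRNAs and 0 lower (8 against 11 samples). miR-200c-3p, an epithelial miRNA, rose by 1.71 (SE 0.49), from 2567 ± 1402 to 8417 ± 5992 CPM (above the normal median in 6 of 8, adjusted p = 0.0498, edgeR). miR-9-5p rose by 1.63 (SE 0.43, 7 of 8, adjusted p = 0.0223) and miR-182-5p by 1.57 (SE 0.39, 7 of 8, adjusted p = 0.0189). miR-663b rose by 1.41 (SE 0.33, 7 of 8, adjusted p = 0.0101) and miR-335-5p by 0.88 (SE 0.22, 6 of 8, adjusted p = 0.0191). miR-9-5p, miR-663b and miR-335-5p entered 17 of the 20 alternatives, as did miR-375. They had too few counts for the stricter filter and the background subtraction, so these calls rest on low counts. miR-148a-3p had a log2 fold change of 2.65 (SE 0.60, 2 of 8, adjusted p = 0.00925) and miR-375 one of 2.45 (SE 0.50, 3 of 8, adjusted p = 0.0034). Without metastasis replicate 16 these were -0.19 (adjusted p = 0.931) and -0.02 (adjusted p = 0.999). In either direction, 54 miRNAs had an unadjusted p under 0.05. Without metastasis replicate 14 the calls were 2, with miR-200c-3p at 1.52, miR-9-5p at 1.31, miR-182-5p at 1.21, miR-663b at 0.94 and miR-335-5p at 0.78 (each adjusted p = 0.105). The call of miR-200c-3p ended without any of 35 libraries, and those of miR-9-5p and miR-335-5p without any of 5 and 6.

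The keratinocyte-enriched miRNAs rose as a list (6 of 7 positive, median 1.08, but 0.44 without scaling; camera adjusted p = 0.0217). The adjusted p was 0.382 with an estimated correlation and 0.161 with the batch as a block. Of these 1 was called and 5 passed over the list alone, and miR-200a-3p stood at 1.36 (7 of 8, adjusted p = 0.0600; 0.88 without replicate 16). The miR-183 cluster rose (3 of 3 positive, 1 called, 3 over the list alone, median 1.18, camera adjusted p = 0.0184; adjusted p = 0.382 with an estimated correlation). miRNAs reported higher in squamous carcinoma rose as a list (12 of 13 positive, 0 called, 1 over the list alone, median 0.69, but 0.27 with the batch as a block and 0.06 within the lower-background batch; camera adjusted p = 0.0184). The adjusted p was 0.382 with an estimated correlation and 0.696 within the lower-background batch, and miR-135b-5p stood at 1.87 (8 of 8, adjusted p = 0.0629; 2.76 without metastatic-class normal skin replicate 1, adjusted p = 0.00119). Melanocyte-enriched miRNAs fell as a list (4 of 4 negative, 0 called and 0 over the list alone, median -0.72, but -0.13 within the lower-background batch; camera adjusted p = 0.0479). The adjusted p was 0.382 with an estimated correlation and 0.866 within the lower-background batch. miR-204-5p stood at -1.39 (adjusted p = 0.414), but at 0.97 within that batch and at -2.41 without metastasis replicate 7. Of the 8 candidates, which are not independent evidence, 1 was called and 4 passed over the list alone (median 0.65, but 0.23 under scaling to the most abundant probes; camera adjusted p = 0.0942). miR-4286 stood at 2.31 (8 of 8 above the normal median, adjusted p = 0.0600; 2.96 without metastatic-class normal skin replicate 29, adjusted p = 0.00966).

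These metastases are the libraries that were compared with the primary tumours, so those comparisons are not independent. With the batch as a block edgeR called 0 miRNAs (46 at an unadjusted p under 0.05), within the lower-background batch 0 (67) and within the higher-background batch 1; without the block DESeq2 called 13, limma 1 and limma with array weights 50. Of the 7 edgeR calls, 5 were shared with DESeq2, 5 with array weights, 0 with limma and 0 with the higher-background batch. With single libraries left out edgeR called 13, 2, 2, 16 and 11 without metastasis replicates 6, 14, 16, 22 and 25, 4 and 12 without metastatic-class primary tumour replicates 12 and 15, and 4 without non-metastatic-class primary tumour replicate 8.

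**Figure D3:**
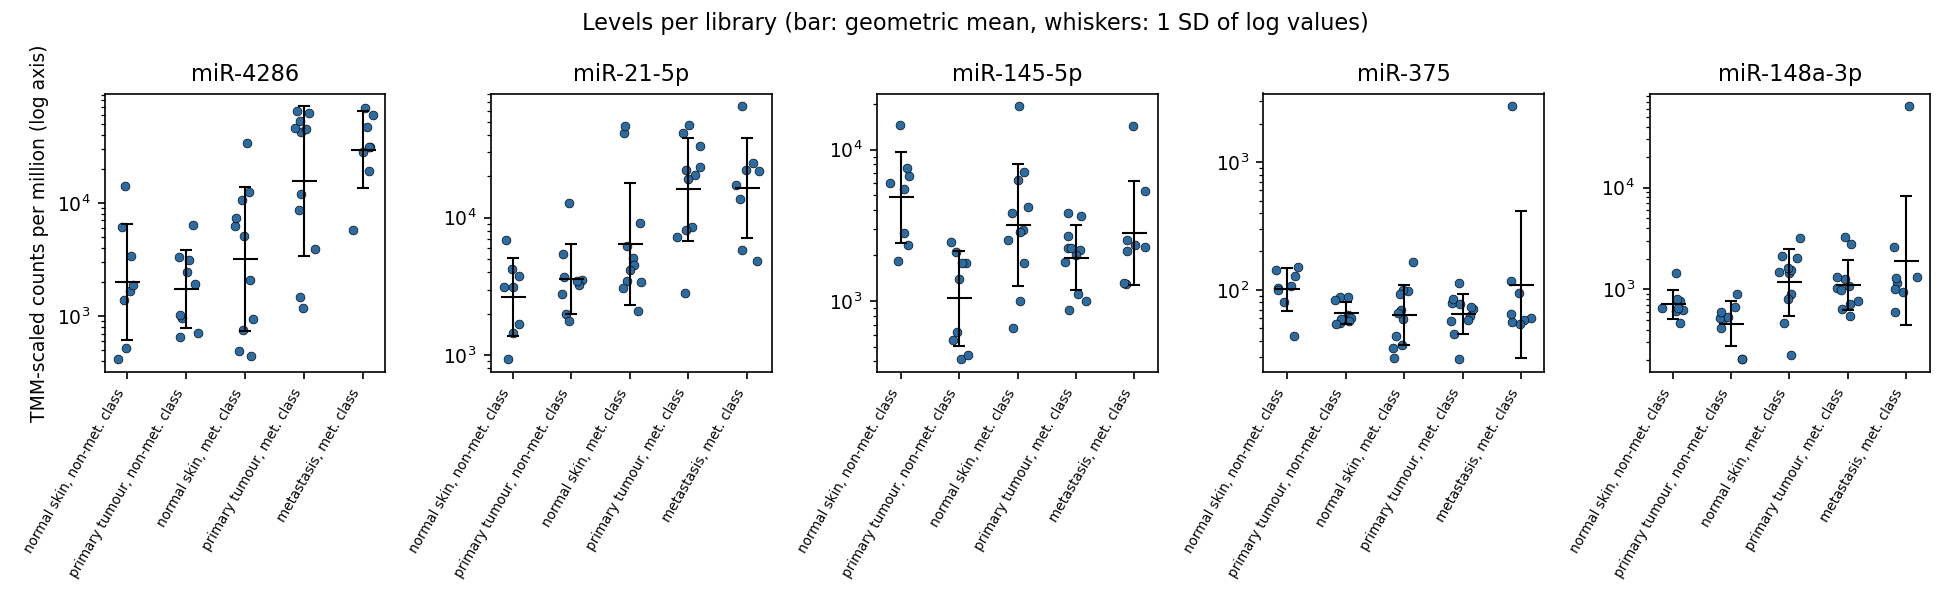
Level (TMM-scaled CPM, log axis) of 5 miRNAs in the 5 groups, with 1 point per library, a bar at the geometric mean and whiskers of 1 SD of the log values. miR-4286 averaged 30811 CPM in metastatic-class and 2285 CPM in non-metastatic-class primary tumours, and the highest metastasis for miR-375 and miR-148a-3p was replicate 16.

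Normal skin of the classes differed in 1 called miRNA (11 metastatic-class against 8 non-metastatic-class samples). miR-548x-3p fell by 0.99 (SE 0.21), from 140 ± 53.0 to 73.7 ± 21.9 CPM. It lay below the median of the other class in 10 of 11 samples (adjusted p = 0.00914, edgeR), and its median counts were 16 and 15.5, near background. miR-3187-3p stood at -0.67 (SE 0.20, 11 of 11 below) and miR-1294 at -0.97 (SE 0.28, 10 of 11), each with an adjusted p = 0.105. miR-548ah-5p stood at -0.77 (SE 0.23, 10 of 11) and miR-215 at -0.83 (SE 0.25, 10 of 11), with the same adjusted p. No list passed (0 with camera, 0 with fry), but within the lower-background batch 3 passed as lower. The smallest camera adjusted p was 0.439, for miRNAs reported lower in squamous carcinoma (median 0.57, -0.21 within the lower-background batch) and for the miR-17-92 family (median 0.31, 0.08 under scaling to the most abundant probes, 0 called, 2 over the list alone). miR-548x-3p stood at -0.79 without non-metastatic-class normal skin replicate 18 (adjusted p = 0.0606), and 2 miRNAs were called without metastatic-class normal skin replicate 4 or 8. Without scaling 180 were higher and 0 lower, DESeq2 called 12 higher and 3 lower, limma with array weights 48 higher and 58 lower, and edgeR called 1 with the batch as a block and 0 within the lower-background batch.

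The tumour-minus-normal change was compared between the classes, and 0 miRNAs differed (edgeR, 29 with an unadjusted p under 0.05; 0 by DESeq2, 0 by limma and 4 by limma with array weights). The difference for miR-4286 was 2.76 (SE 0.98), for miR-196a-5p 1.61 (SE 0.56) and for miR-106b-5p of the miR-17-92 family 1.36 (SE 0.48). It was -1.51 for miR-1322 (SE 0.45), -1.22 for miR-187-3p (SE 0.43) and -0.90 for miR-4443 (SE 0.32). Each of these had an adjusted p = 0.426. The let-7 family had a higher change in the metastatic class as a list (9 of 9 positive, median 0.58, but 0.07 without scaling; camera adjusted p = 0.0027; adjusted p = 0.485 with an estimated correlation). miRNAs reported higher in squamous carcinoma did too (13 of 13 positive, median 0.56, but 0.11 within the lower-background batch; camera adjusted p = 0.00356; adjusted p = 0.485 with an estimated correlation). In each list 0 were called and 0 passed over the list alone, and with fry neither passed (adjusted p = 0.332 and 0.325). In the simulated data, which held no batch and no outlying library, a 2-fold difference of changes was recovered in 47% of probes.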

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

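The tests of single libraries, of yield and batch, and of the fibroblast and smooth muscle list were chosen after the results were seen. The counts of other splits of the samples were written before. The test for cells of another type was recorded as written before, but it names miRNAs and a library found in the results, so it was not independent of them. A sample is listed here where its gap to the nearest other sample of its group exceeded Dixon's critical value, given as a share of the group's range. The metastatic-class primary tumours and the metastatic-class normal skin, with 11 samples each, were not tested in this way. Of 112 sets of values tested in the other groups, 11 did, and chance alone gives about 1 in 20 groups.

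Metastasis replicate 16 was the highest of 8 for miR-375 (0.818), miR-148a-3p (0.689) and miR-30a-5p (0.533). In non-metastatic-class normal skin, replicate 1 was the highest of 8 for miR-497-5p (0.575) and replicate 13 for miR-18a-5p (0.610). In non-metastatic-class primary tumours, replicate 5 was the highest of 9 for miR-214-3p (0.498), and replicate 17 the lowest for miR-421 (0.503). Replicate 8 of that group was the highest for miR-3195 (0.672), miR-4516 (0.654) and miR-630 (0.622) and the lowest for miR-342-3p (0.501). The sample with contradicting labels, which entered no comparison, had 38 probes above each of the 19 normal skin libraries and 23 below each, where 19.4 are expected by chance each way. The 413 probes not kept were screened by another rule, which took only those below 20 counts in every normal skin library, and it flagged 0.

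Between the primary tumours, 51 miRNAs were higher in the metastatic class, whose libraries also held more signal. The technical batch alone is argued against: with the batch as a block 50 of the 51 stayed called. A lower yield over background in the non-metastatic class cannot be told apart from a class difference. Under scaling to the most abundant probes the median log2 fold change of the 51 went from 1.39 to 0.69 (median SE 0.32), between the bounds set for the 2. That scaling shifted the median of all 387 probes by -0.71. The drop of the 51 thus follows from the scaling factors and cannot decide between them. Under that scaling 26 stayed called, and 17 of these were also called in a separate run with background subtracted, which tested only 204 probes. With log2 total as a covariate, which itself follows the class, 4 of the 51 stayed called. A difference between metastatic and non-metastatic tumours may contribute, as a hypothesis found on the same data, and RNA degradation or storage, which the labels do not give, were not tested.

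Fibroblast- and smooth-muscle-enriched miRNAs were lower in primary tumours than in normal skin. Over all libraries the mean log2 level of the list differed by -0.94 (exact permutation p = 0.000602), and with the batch as a block by -0.66 (permutation p = 0.0166), which counts against the batch as the only cause. Within the lower-background batch it differed by -0.435 (18 against 11 libraries, exact permutation p = 0.139), neither near 0 nor past the threshold, so how much the batch adds cannot be told with so few normal skin libraries. A lower share of fibroblasts and smooth muscle cells in the tumour samples and changes within those cells were not tested apart, and 2 of the 8, miR-145-5p and miR-214-3p, are also in the list reported lower in squamous carcinoma.

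miR-375 and miR-148a-3p were called higher in metastases. Without metastasis replicate 16, 0 of these calls were left in either comparison, so the calls rest on that library. Cells of another type in it could raise them: it was the highest of 8 metastases for 1 of 6 leukocyte-enriched miRNAs (miR-142-3p, 3334 CPM). It was the lowest for 2 of 7 keratinocyte-enriched ones (miR-203, 192 CPM, and miR-205-5p, 5085 CPM) and the highest for 4 others of the 7 (miR-200a-3p, miR-200b-3p, miR-141-3p and miR-429). These counts of highest leukocyte-enriched and lowest keratinocyte-enriched miRNAs are more than the bound set against this explanation and less than the bound set for it, so it stays open. Such counts leave out size: each of the 6 leukocyte-enriched miRNAs lay above the mean of the other 7 metastases, by 0.23 (miR-155-5p) to 4.14 (miR-150-5p) on the log2 scale. The keratinocyte-enriched list went both ways against that mean. miR-203 stood at -3.80 and miR-205-5p at -2.23, while the miR-200 family members stood at 1.20 (miR-429) to 2.46 (miR-200b-3p). A count of its lowest members therefore cannot decide on epithelial cells that hold the miR-200 family but little miR-203 and miR-205-5p. Where the metastasis was taken was not used here, and a difference of the tumour itself was not tested.

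Other splits of the same libraries were counted, 100 for each comparison with the real split included. No split but the real one gave as many calls for primary tumours against normal skin (real 8, highest other 3). The same held for the primary tumours of the classes (real 62, highest other 40), where 26 other splits gave some calls. Chance is unlikely there but not excluded, as 100 splits cannot show a share below 1 in 100. They also treat samples as independent, though some may come from 1 patient. These splits did not keep the batch, which was uneven; in 100 splits that did, chosen after the results were seen, again only the real ones gave as many (highest other 6 and 12). For tumours against normal skin this leaves the share of the batch open: with it as a block 0 miRNAs were called, while the median log2 fold change of the 8 went from -1.06 to -0.85 (median SE 0.28). Chance cannot be excluded for metastases against primary tumours (70 splits gave as many as the real 2, highest other 26). Nor can it for metastases against normal skin (7 splits, real 7, highest other 23) and normal skin of the classes (9 splits, real 1, highest other 8). For the difference of changes the real count was 0, so all 100 splits had to give as many and the count tests nothing (highest other 3). Splits that called several times the real count, in the comparisons of metastases and of normal skin, point to a structure of the samples, which was not traced and may be a single library.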

How the results depend on the processing

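The batch block, the single batches, the background subtraction, the 2 combined settings and the left-out libraries were chosen after the data were seen; the other alternatives were planned. Counts of called miRNAs are given in a fixed order: tumour against normal skin, primary tumours of the classes, metastasis against primary tumour, metastasis against normal skin, normal skin of the classes, and difference of changes. They were 8, 62, 2, 7, 1 and 0 in the report. No scaling gave 18, 84, 2, 0, 180 and 0. Scaling to the most abundant probes gave 11, 216, 2, 4, 0 and 0. Quantile normalization gave 8, 46, 2, 3, 1 and 0, and median-ratio size factors 7, 61, 2, 6, 1 and 0. No filter gave 6, 57, 3, 4, 5 and 0, and the stricter filter 11, 47, 3, 7, 0 and 0. Equal counts can hold other miRNAs: for metastasis against normal skin only 1 of the report's 7 was among the 7 with the stricter filter. A prior count of 5 gave 8, 62, 2, 7, 1 and 0. limma gave 3, 45, 0, 1, 1 and 0, with a pseudocount of 0.5 it gave 3, 41, 0, 1, 1 and 0, and with 16 it gave 5, 47, 0, 1, 0 and 0. None of these single calls for metastasis against normal skin was among the report's 7. Array weights gave 52, 50, 0, 50, 106 and 4. DESeq2 gave 14, 71, 0, 13, 15 and 0. A fit of only the groups compared gave 11, 68, 0, 0, 0 and 0. log2 total as a covariate gave 0, 5, 2, 8, 0 and 0. The batch as a block gave 0, 64, 2, 0, 1 and 0, and the lower-background batch 0, 66, 3, 0, 0 and 0. The higher-background batch gave 0 and 1 for the comparisons of metastases with tumour and with skin; the others had too few libraries there. That 1 call was not among the report's 7 either. Background subtraction, which left 204 probes, gave 4, 31, 1, 1, 0 and 0. The abundant-probe scaling gave 1, 210, 2, 0, 0 and 0 with the batch block and 14, 44, 1, 1, 0 and 0 with the stricter filter. Without a class term the tumour comparison had 22 calls. With single libraries left out the counts ranged from 5 to 15, 45 to 78, 0 to 4, 2 to 16, 0 to 2 and 0 to 0. The title number as a block gave 4 calls for primary tumours (3 higher, 1 lower) and 0 for normal skin. With it the 4 and 2 pairs that share a number correlated at -0.105 to 0.274 and 0.0241 to 0.0999 after group means were removed, and 1 and 1 sample correlated best with its own number. Titles are numbered separately within each class, so a number shared across classes does not tie samples. Calls lost under that block therefore say nothing about pairing. Fewer libraries enter that block and the single batches; the cause was not tested for the other settings.

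Called lists in the same order were 5, 5, 5, 4, 0 and 2 in the report. An estimated correlation gave 1, 0, 0, 0, 0 and 0, and fry 4, 8, 0, 0, 0 and 0. No scaling gave 5, 3, 4, 4, 0 and 2, the abundant-probe scaling 6, 8, 6, 5, 0 and 6, quantile normalization 5, 0, 5, 2, 0 and 1, and median-ratio size factors 5, 5, 5, 4, 0 and 2. The batch block gave 7, 4, 5, 2, 0 and 6, and the lower-background batch 5, 9, 7, 7, 3 and 5. Without metastasis replicate 16 there were 5, 6, 2, 5, 0 and 2. The cause was not tested. Against TMM, no scaling shifted the median log2 fold change of all probes by -0.33, 0.51, 0.15, -0.30, 0.78 and -0.28. Scaling to the most abundant probes shifted it by -0.71 for primary tumours, -0.25 for metastases against skin, -0.19 for normal skin and -0.52 for the difference of changes.

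Of the values of called miRNAs under the alternatives, 101 of 157 kept direction and call in the tumour comparison, 481 of 688 between primary tumours, 23 of 37 and 42 of 126 in the comparisons of metastases and 8 of 17 in normal skin. Of these, 56, 203, 12, 79 and 9 kept the direction but lost the call. miR-4286 and miR-421 stayed called between primary tumours under 20 of 20 alternatives. Of the miRNAs not called, 23 of 112, 9 of 100, 3 of 140, 11 of 80, 5 of 69 and 2 of 109 values passed in the 6 comparisons.

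Directions turned as follows, and the cause was not tested. Between primary tumours, the title number as a block, which does not tie related samples, gave miR-204-5p -0.58, miR-1286 0.038, miR-205-5p -0.57 and miR-150-5p -1.43. miR-3195 was 0.27 with DESeq2 and miR-342-3p -0.012 under quantile normalization. No scaling gave miR-1915-3p 0.21 and miR-4516 0.21, and no filter gave miR-1915-3p 0.026. miR-205-5p was -0.33 under the abundant-probe scaling, -0.37 under quantile normalization, -0.15 with the stricter filter, -0.21 with log2 total and -0.27 with background subtracted. With the abundant-probe scaling it was -0.26 with the batch block and -0.33 with the stricter filter. miR-150-5p was -0.19 under the abundant-probe scaling, -0.023 with the batch block added, -0.19 with the stricter filter added and -0.40 under quantile normalization. With limma it was -0.22, with pseudocounts of 0.5 and 16 it was -0.22 and -0.15, and with array weights -0.17. For metastases against primary tumours DESeq2 gave miR-148a-3p -0.10, and no scaling gave miR-155-5p 0.11. There the higher-background batch gave miR-148a-3p -0.15, miR-29c-3p -0.30, miR-30a-5p -0.28, miR-99a-5p -0.10, miR-155-5p 0.29 and miR-195-5p -0.63. For metastases against normal skin DESeq2 gave miR-148a-3p -0.27 and miR-375 -0.032. There the higher-background batch gave miR-148a-3p -0.90, miR-375 -0.34, miR-200c-3p -0.066 and miR-200a-3p -0.17, and the lower-background batch gave miR-204-5p 0.97. In normal skin miR-3187-3p was 0.15 without scaling. Without non-metastatic-class primary tumour replicate 8 miR-3195 was 0.26 and miR-4516 0.35. Without metastasis replicate 16 miR-148a-3p was -0.040 against primary tumours and -0.19 against normal skin, and miR-375 was -0.018 against normal skin. Some calls between primary tumours lay near background: 9 of the 11 lower and 10 of the 51 higher miRNAs had a median below 20 counts.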

Other observations

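The test of neighbouring genes was chosen after the results were seen. miRNAs whose genes lie close together were called together between the primary tumours in more pairs than permuted calls gave. Of 235 pairs of kept miRNAs with genes within 10 kb of each other, 14 were both higher in the metastatic class, against 6.12 expected when the calls were permuted among miRNAs of like abundance (permutation p = 0.0088). In 39 more pairs only 1 member was called higher. The pairs included miR-106b-5p (1.79) with miR-93-5p (1.20) and miR-25-3p (0.81), which share a host gene, and miR-374b-5p (1.42) with miR-421 (1.84). miR-16-5p (1.58) was called with miR-15b-5p (1.75), and miR-29a-3p (1.58) with miR-29b-3p (1.71). A candidate explanation is that such clusters change as units, but signal shared between similar probes of a family was not excluded. Genes were found for 377 of the 387 probes in the GRCh38.p14 annotation.

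Metastasis replicate 16 differed from the other 7 metastases in more than its called miRNAs. Its miR-148a-3p level was 63478 CPM (10224 counts) against 599 to 2575 CPM in the others, and its miR-375 level 2744 CPM against 54.2 to 118 CPM. miR-451a stood at 33254 CPM (546 to 5945 in the others), miR-99a-5p at 11356 CPM (126 to 5308) and miR-200b-3p at 6401 CPM (361 to 3225). miR-29c-3p stood at 4638 CPM (118 to 996) and miR-30a-5p at 4806 CPM (235 to 974). Of the 387 probes, 16 were at least 2-fold above and 2 at least 2-fold below each of the other 7.

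The sample with contradicting labels had 230326 counts in total. Its miR-4286 level was 37107 CPM, against 412 to 33530 CPM in the 19 normal skin libraries and medians of 30607 CPM in metastases and 1903 CPM in non-metastatic-class primary tumours. miR-21-5p stood at 58808 CPM (922 to 46182 in normal skin, medians 19421 and 3456 in the other 2 groups) and miR-200a-3p at 1573 CPM (101 to 421, medians 474 and 131). miR-145-5p stood at 3448 CPM (658 to 19162, medians 2298 and 1396), miR-205-5p at 29766 CPM (6757 to 85767, medians 28495 and 16096) and miR-203 at 3667 CPM (1479 to 17319, medians 1531 and 2895).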
